A study of Homo sapiens with 12 samples.

How the data were processed

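RNA from U937 cells, a human myeloid leukemia line, was measured on 12 expression arrays. The 4 groups of 3 biological replicates were cells given the DMSO vehicle and cells given JS-K for 90 min, 4 h or 24 h. Per the labels, RNA was taken with Trizol, and 200 ng was labelled with biotin from random hexamers by a whole-transcript kit. The probe set names, by contrast, are those of an array design that reads the 3' ends of transcripts, and how the kit was used with it is not stated. The authors deposited 1 value per probe set and array on the log2 scale, made with GCRMA (background correction from probe sequence, quantile normalization and summary of probes) in Affymetrix Expression Console, with no version given. The deposited log2 values were used without further normalization. The quantiles of the arrays were checked and were close but not identical. Intensity files and the metabolite part of the series were not analysed here.

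The table held 54675 probe sets. Of these, 41097 were listed with 1 gene symbol, 1801 with several and 11777 with none, and 41043 of those with 1 symbol matched a RefSeq gene of the human assembly GRCh38.p14 by gene identifier. For the 10523 genes with more than 1 such probe set, the probe set with the highest mean over the 12 arrays stood for the gene, which gave 19775 genes. No filter on level was set. A mean of 4 on the log2 scale marked low signal, and 10224 genes (51.7%) lay under it.

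Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the spread on the mean), with all 12 arrays in 1 fit. The fit had 8 residual and 3.97 prior degrees of freedom. Each JS-K time was compared with vehicle, 4 h was compared with 90 min and 24 h with 4 h, and a moderated F test asked whether any group differed. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at an adjusted p under 0.05. These p-values measure the spread between these samples. Errors are standard errors (SE) of the fit for differences and standard deviations (SD) of 3 arrays for levels, and a fold is 2 raised to the log2 difference. The number of arrays limits the precision.

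Before the data were examined, 38 gene lists were fixed, with 867 entries of which 785 were measured, as were the groups, the tests, the alternatives and the genes to be named. The lists cover redox and stress responses, metabolism, the cell cycle, cell death, inflammation and markers of myeloid and other cell types. Each list was tested with limma's camera (preset correlation between genes of 0.01), with adjustment over all lists and the 5 comparisons, 190 tests in all. Camera was also run with a correlation estimated from the data, and limma's fry, which tests whether the genes of a list move on balance in 1 direction without a comparison with other genes, was run beside it. Calls within a list are given from the adjustment over all genes and adjusted over the list alone. List medians were also set against 10000 random lists matched on level in 20 bins.

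Named genes followed a rule. Against vehicle they were the 8 largest rises and 8 largest falls among called genes whose 3 JS-K arrays all lay beyond the 3 vehicle arrays, without uncharacterised, olfactory receptor and small RNA symbols. Between times they were the 5 largest in each direction. Up to 4 called members with the largest change were named per described list, together with 20 fixed genes of redox, stress and cell cycle responses. Of these, 19 were measured. HSPA1A had only probe sets shared with other symbols and was not analysed here.

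The procedure was tested on simulated data of 19775 genes with the same layout. It recovered 92 of 100 genes changed 2-fold and 100 of 100 changed 4-fold. Of 205 genes called, 13 (6.34%) were unchanged, and 1 gene was called in a comparison without changes. Of 38 unchanged lists of random genes, camera called 1. Each gene was drawn on its own, without correlation between genes or a shift common to an array. These rates therefore do not cover such effects. Overlap between calls was set beside 20 simulations of unchanged groups that share the vehicle arrays.

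Alternatives were a constant spread, removal of the dimmest genes (3 equal parts by mean, the lowest left out), the mean of a gene's probe sets, every probe set on its own, quantile normalization, subtraction of array medians, the replicate number as a block, array weights, the 6 arrays of a comparison alone, a test against a fold of 1.5 (limma's treat) and leaving out in turn each array of the groups compared. A fit of genes with a mean of at least 4, a count of called genes changed at least 2-fold and the fit without JS-K 4 h replicate 2 for the comparisons of 90 min and 24 h with vehicle, which do not use that array, were added after seeing the data. Control probe sets for added spikes and ribosomal RNA were averaged per array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.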

Results

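Gene expression was measured in U937 cells, a human myeloid leukemia line with monocyte-like features, after exposure to JS-K, a prodrug that releases nitric oxide, or to its DMSO vehicle. There were 3 arrays each for vehicle and for 90 min, 4 h and 24 h of JS-K. The title of the series places the work in the study of redox balance and death of cancer cells. The labels state neither the dose of JS-K nor how long the vehicle cells were exposed. With a single vehicle group there is no vehicle matched to each exposure time. Time in culture therefore cannot be told apart from JS-K in these comparisons. Array medians lay between 2.84 and 2.99 on the log2 scale, except for replicate 2 of the 4 h group, which was higher, and 61.4% to 62.1% of the probe sets of each array lay under 4. Across probe sets, which are not independent replicates, correlations were 0.993 to 0.998 within groups and 0.973 to 0.995 between groups. The first principal component held 67.2% of the variance and placed the vehicle arrays at −36.1 to −35.1, the 90 min arrays at −25.1 to −23.0, the 4 h arrays at 0.280 to 10.5 and the 24 h arrays at 55.4 to 57.8. Differences are given as log2 differences ± SE between means of 3 arrays (n = 3 and 3).

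The groups also differed in control probe sets. The poly-A spikes, bacterial transcripts added to a sample before labelling, averaged 3.04 ± 0.05 in vehicle and 3.08 ± 0.06 at 90 min, but 7.02 ± 0.15 at 4 h and 8.47 ± 0.05 at 24 h (SD, n = 3). The hybridization spikes, added later, averaged 9.96 ± 0.18, 10.03 ± 0.18, 10.21 ± 0.30 and 11.70 ± 0.04 in the same order. Probe sets for 28S ribosomal RNA averaged 9.04 ± 0.20 in vehicle and 11.19 ± 0.24 at 24 h. The 3' minus 5' difference of ACTB probe sets, a measure of RNA quality and labelling, averaged 0.80 ± 0.03, 0.83 ± 0.02, 0.96 ± 0.17 and 0.96 ± 0.04 in that order. For GAPDH it was 0.13 ± 0.01 at 24 h and between −0.15 and 0.03 on the other arrays. Vehicle and 90 min arrays thus share their spike status, which the 4 h and 24 h arrays do not. Among the 4 h arrays, replicate 2 had the highest median and the lowest upper quartile (6.20) of the series, the highest ACTB difference (1.15) and correlations of no more than 0.993 with the other arrays of its group. Levels under 4 are low signal, near the array medians and the trp probe sets, for which no spike was added (2.53 in vehicle). A difference with 1 end there and the other above 4 is read as a lower bound. With both ends under 4 it is not, since the trp probe sets themselves averaged 2.66 at 4 h and 2.63 at 24 h.

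**Figure D1:**
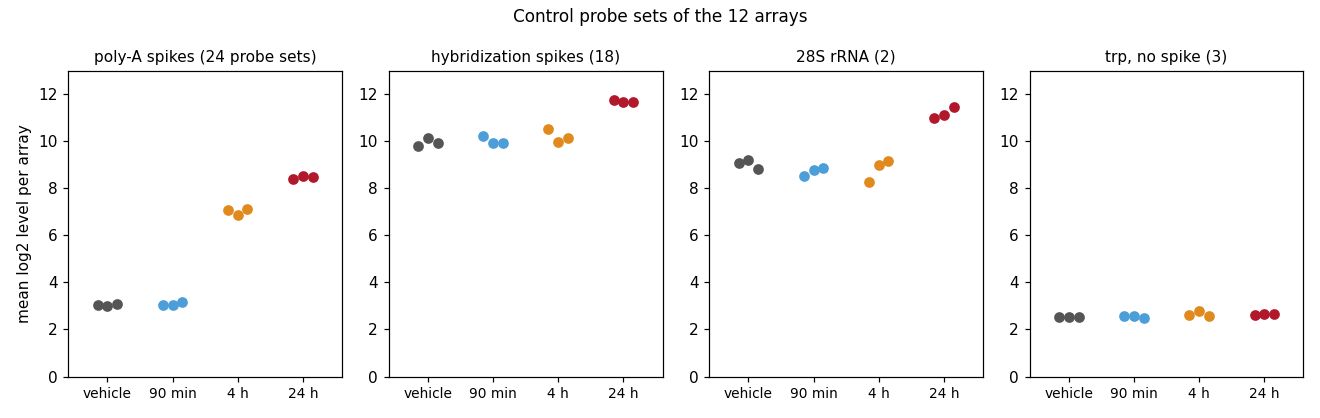
Mean log2 level of control probe sets on each of the 12 arrays (points), by group on the x axis. The poly-A spikes lie near 3.04 in vehicle and 3.08 at 90 min, against 7.02 at 4 h and 8.47 at 24 h, while the trp probe sets, for which no spike was added, stay between 2.53 and 2.66 in group means.

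The comparison of 90 min with vehicle asks which genes respond first. CXCL8, which encodes the neutrophil chemoattractant interleukin-8, rose 24.6-fold, from a level of 6.39 ± 0.07 to 11.02 ± 0.04 (SD, n = 3). Transcription factor genes of the immediate early response rose with it: JUN by 3.38 ± 0.08, FOS by 3.29 ± 0.34 and EGR3 by 3.40 ± 0.22. At the same time genes of cholesterol synthesis fell, 13 of 18 measured, and MYC, a driver of growth and proliferation, fell by 1.48 ± 0.08. HMOX1, the heme oxygenase induced by oxidative stress, rose by 2.41 ± 0.30 from a level under 4.

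The other largest rises at 90 min were TRIB1 (3.99 ± 0.15), a pseudokinase gene, PRDM1 (3.91 ± 0.18), a transcriptional repressor of differentiating blood cells, MMP1 (3.71 ± 0.12), an interstitial collagenase, and FZD7 (3.46 ± 0.12), a Wnt receptor. TRIB1, PRDM1 and EGR3 rose from levels under 4, and for PRDM1 and HMOX1 these (2.62 and 2.53) lay near the trp probe sets. The largest falls were ACSM3 (−2.43 ± 0.14), SAMD13 (−2.02 ± 0.12), TCEA2 (−1.99 ± 0.22), the long non-coding RNA DPH5-DT (−1.93 ± 0.23), ATP6AP1L (−1.91 ± 0.18), SYTL1 (−1.90 ± 0.15), PWAR6 (−1.84 ± 0.21) and NHSL1 (−1.81 ± 0.32). ACSM3, SAMD13, SYTL1 and PWAR6 fell to levels under 4, SAMD13 to one under that of the trp probe sets (2.27). On the GRCh38.p14 assembly, CXCL8 lies on chromosome 4 (73740569 to 73743716), MYC on chromosome 8 (127735434 to 127742951), HMOX1 on chromosome 22 (35381096 to 35394207) and CDKN1A on chromosome 6 (36676463 to 36687332).

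Of 30 measured immediate early genes, 18 rose and 3 fell, and 19 and 3 did so adjusted over the list alone (median 0.83, camera adjusted p = 3.41e-15, adjusted p = 0.0130 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 3.22 ± 0.20 from a level under 4. The 13 cholesterol synthesis genes that fell, 15 adjusted over the list alone, included HMGCS1 (−1.58 ± 0.11), which makes the precursor of mevalonate, DHCR7 (−1.56 ± 0.10) and MSMO1 (−1.49 ± 0.06), enzymes of late steps, and the sterol transporter STARD4 (−1.43 ± 0.10). The list median was −0.82 (adjusted p = 4.69e-25, and 0.00654 with an estimated correlation). Of 34 genes of G2 phase and mitosis, 17 rose by small amounts, 20 with 1 fall adjusted over the list alone (median 0.29, adjusted p = 1.46e-12, adjusted p = 0.0130 with an estimated correlation). Among them CCNB1, a cyclin of mitotic entry, rose by 0.41 ± 0.05 and ANLN, an actin-binding protein of the cleavage furrow, by 0.50 ± 0.08. MCM2, a subunit of the replicative helicase, gave −0.29 ± 0.09 (adjusted p = 0.0789). Of 21 monocyte and macrophage genes, 9 rose, 10 adjusted over the list alone (median 0.16, adjusted p = 6.84e-08, adjusted p = 0.0328 with an estimated correlation). The scavenger receptor CD36 rose by 1.88 ± 0.08, the calcium-binding S100A8 and S100A9 by 1.75 ± 0.14 and 1.11 ± 0.11, and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by 1.28 ± 0.24.

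Of 23 NF-κB and inflammatory genes 3 rose and 1 fell, also adjusted over the list alone (median 0.04, adjusted p = 0.0326, adjusted p = 0.433 with an estimated correlation). Besides CXCL8 the rises were those of the chemokines CXCL2 (2.64 ± 0.19) and CCL2 (1.75 ± 0.07), and REL, a subunit of NF-κB itself, fell by 0.55 ± 0.11. The list call ended in 6 of 15 alternatives (adjusted p up to 0.426), among them those without vehicle replicate 1 (0.0585), 90 min replicate 3 (0.0792) or 4 h replicate 2 (0.109).

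Redox genes were divided at 90 min. Of 28 NRF2 targets, genes of the antioxidant response, 9 rose and 19 did not pass the test, against 10 rises and 1 fall adjusted over the list alone (median 0.07, adjusted p = 3.97e-05, adjusted p = 0.132 with an estimated correlation). Among them NQO1, a quinone reductase, rose by 0.95 ± 0.09, GCLM, the regulatory subunit of glutathione synthesis, by 0.68 ± 0.09, the cystine importer SLC7A11 by 0.72 ± 0.09, the autophagy receptor SQSTM1 by 0.73 ± 0.07, the sulfiredoxin SRXN1 by 0.56 ± 0.13 and the thioredoxin reductase TXNRD1 by 0.28 ± 0.07. For GCLC, the catalytic subunit of glutathione synthesis, the difference was 0.27 ± 0.11 (adjusted p = 0.166). Within the glutathione list 4 genes rose and 5 fell, with the same counts adjusted over the list alone, and the list test gave an adjusted p of 0.415. CTH (−1.13 ± 0.12) and CBS (−1.12 ± 0.17), the enzymes that make cysteine from homocysteine, fell. Of 20 genes of glutathione transferases and their export pumps 3 fell and 17 did not pass, with GSTA4 down the most (−1.41 ± 0.16), and the list median of 0.01 and mean of −0.15 differed in sign (test down, adjusted p = 0.353). GSTP1, the pi-class transferase, gave −0.26 ± 0.13 (adjusted p = 0.344). In the thioredoxin and peroxiredoxin list 3 genes rose and 3 fell (adjusted p = 0.229), the largest fall being that of TXNIP (−1.19 ± 0.08), an inhibitor of thioredoxin.

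Chaperone genes of the endoplasmic reticulum rose, 11 of 21, or 13 adjusted over the list alone (median 0.29, adjusted p = 1.34e-10, adjusted p = 0.0751 with an estimated correlation). Among them SDF2L1 changed by 0.95 ± 0.20, CRELD2 by 0.94 ± 0.10 and DNAJB11 by 0.83 ± 0.09. Of 22 heat shock genes 5 rose, 7 adjusted over the list alone (adjusted p = 0.00412, adjusted p = 0.306 with an estimated correlation). Among them were the cochaperone DNAJA1 (0.58 ± 0.08) and HSPH1 (0.52 ± 0.06), while DNAJB1 gave 0.33 ± 0.10 (adjusted p = 0.0502). Targets of ATF4, the transcription factor of amino acid stress, moved both ways: 7 of 34 rose and 13 fell, 7 and 14 adjusted over the list alone (median −0.06, adjusted p = 0.0178, adjusted p = 0.579 with an estimated correlation). PPP1R15A, a phosphatase subunit of the stress response, rose by 1.76 ± 0.16 and ATF5 by 1.16 ± 0.17, while ASNS, asparagine synthetase, fell by 1.48 ± 0.25 and the pseudokinase TRIB3 by 0.39 ± 0.10. DDIT3 (0.03 ± 0.13, adjusted p = 0.949) and CHAC1 (−0.05 ± 0.07, adjusted p = 0.930) did not pass the test. CHAC1 lay under the level of the trp probe sets in all 4 groups (means of 2.18 to 2.31). A fall or a small rise of CHAC1 could therefore not be seen, here or in the later comparisons. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 2.83-fold, but the p53 target list, with 3 rises and 2 falls among its genes, did not pass (adjusted p = 0.624). Of 9 antiapoptotic genes 3 rose, 4 adjusted over the list alone (adjusted p = 0.00802, adjusted p = 0.165 with an estimated correlation). Among them BCL2A1 changed by 1.08 ± 0.05 and MCL1 by 0.88 ± 0.07. Of 17 pentose phosphate and NADPH genes 6 fell, 8 adjusted over the list alone (median −0.24, adjusted p = 2.7e-05, adjusted p = 0.0740 with an estimated correlation). IDH1 fell by 0.43 ± 0.05. The lists of glycolysis (1 higher, adjusted p = 0.288) and nucleotide synthesis (2 higher, 1 lower, adjusted p = 0.945) did not pass.

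At 90 min 796 genes were higher and 1111 lower than in vehicle, with 120 and 156 of them changed at least 2-fold, and with array medians subtracted the counts were 610 and 622. For 26.9% of all genes the arrays of the groups did not overlap, against 10% by chance for a single gene. A shift common to an array moves many genes together. This share and those of the later comparisons therefore do not count genes that respond. Of the 38 lists 18 were called, and 4 of these hold with an estimated correlation (cholesterol synthesis, immediate early, G2 phase and mitosis, monocyte). With the preset correlation, 2 of 15 alternatives ended the calls of ATF4 targets (adjusted p up to 0.249), heat shock (0.147) and antiapoptotic genes (0.331). The count of lower genes was 715 without vehicle replicate 3 and 631 without 90 min replicate 2. The call of SRXN1 ended without vehicle replicate 3 (adjusted p = 0.0554) or 90 min replicate 1 (0.0733), that of TXNRD1 without vehicle replicate 2 (0.114) or 3 (0.0702) or 90 min replicate 1 (0.0624), 2 (0.0761) or 3 (0.0989), and that of TRIB3 without vehicle replicate 1 (0.0817), 2 (0.0881) or 3 (0.0786) or 90 min replicate 2 (0.138) or 3 (0.0936).

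**Figure D2:**
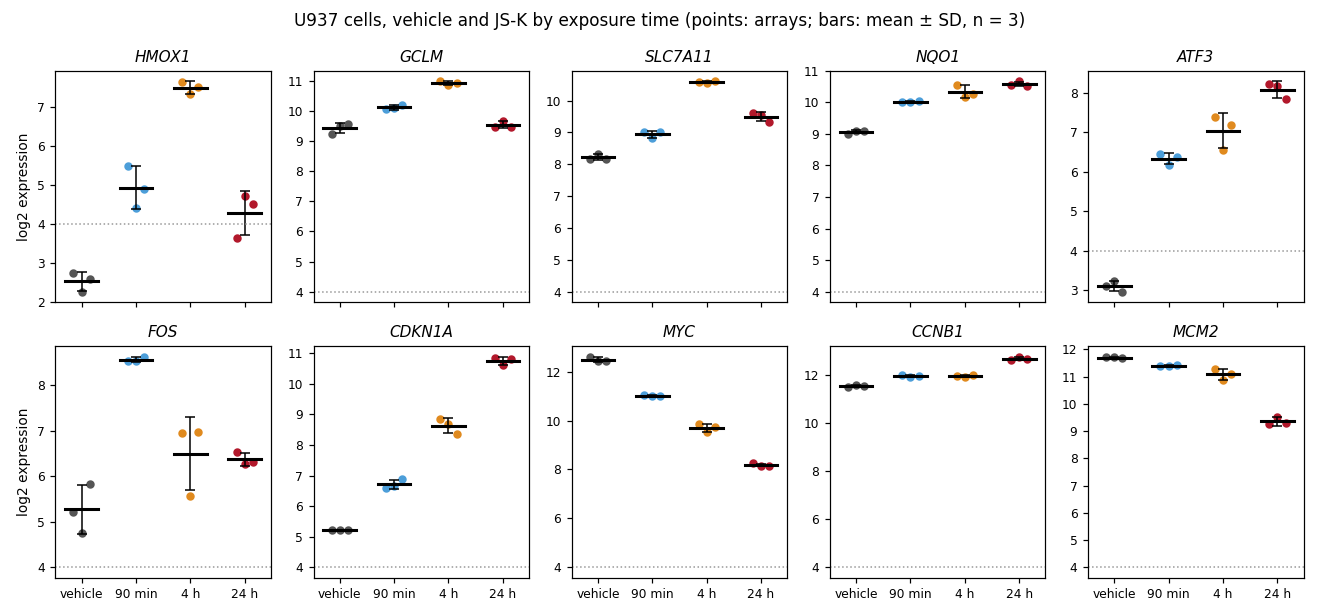
Log2 level (y axis) of 10 of the fixed genes in vehicle and after 90 min, 4 h and 24 h of JS-K. Points are arrays, bars give the mean and SD of 3 arrays, and the dotted line marks a level of 4, with HMOX1 at 2.53 ± 0.25 in vehicle and 7.51 ± 0.16 at 4 h, and MYC at 12.49 ± 0.10 in vehicle and 8.18 ± 0.06 at 24 h.

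The comparison of 4 h with vehicle covers a middle time. CXCL8 rose 44.3-fold (5.47 ± 0.06), HMOX1 at least 31.5-fold (4.98 ± 0.30) and ATF3 by at least 3.93 ± 0.20. Genes for making ribosomes fell, 26 of 29 measured, and so did cholesterol synthesis genes, 15 of 18. MYC fell 6.88-fold, from 12.49 ± 0.10 to 9.71 ± 0.15 (SD, n = 3). The 4 h arrays held poly-A spikes (7.02) that the vehicle arrays lacked (3.04).

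Further large rises were TRIB1 (5.21 ± 0.15), C5AR1 (4.40 ± 0.15), the receptor for complement fragment C5a, EMP1 (4.34 ± 0.24), an epithelial membrane protein gene, IER3 (3.81 ± 0.22), an early response gene, and FCAR (3.72 ± 0.18), the Fc receptor for IgA. TRIB1, HMOX1, C5AR1, EMP1, ATF3 and IER3 rose from levels under 4. The vehicle levels of HMOX1 (2.53) and IER3 (2.65) were near that of the trp probe sets (2.53), and the order of these 6 among the largest is not exact. The largest fall was that of MARS2 (−3.61 ± 0.21), the mitochondrial methionyl-tRNA synthetase, followed by TWNK (−3.01 ± 0.38), a helicase of mitochondrial DNA replication. MYC (−2.78 ± 0.08), ASH1L-AS1 (−2.77 ± 0.21), DPH5-DT (−2.57 ± 0.23), ZNF133 (−2.54 ± 0.27), DHODH (−2.53 ± 0.21), the mitochondrial enzyme of pyrimidine synthesis, and MCM3AP-AS1 (−2.45 ± 0.28) came next. DHODH and DPH5-DT fell to levels under 4, and another probe set of DPH5-DT was called in the opposite direction.

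The fall of ribosome biogenesis genes (26 also adjusted over the list alone) had a median of −0.68 (adjusted p = 2.95e-18, adjusted p = 0.122 with an estimated correlation). It included POLR1B (−1.90 ± 0.09) and POLR1C (−1.81 ± 0.16), subunits of RNA polymerase I, and the assembly factors RRS1 (−1.71 ± 0.12) and WDR74 (−1.59 ± 0.13). Cholesterol synthesis genes had a median of −1.30, with 16 lower adjusted over the list alone (adjusted p = 1.47e-17, adjusted p = 0.0120 with an estimated correlation), and HMGCS1 (−2.42 ± 0.11), MSMO1 (−2.26 ± 0.06) and the sterol sensor partner INSIG1 (−2.10 ± 0.08) fell. Of 31 genes of the G1/S transition and DNA replication 19 fell and 2 rose, 20 and 2 adjusted over the list alone (median −0.37, adjusted p = 6.34e-07, adjusted p = 0.353 with an estimated correlation). The helicase subunits MCM3 (−0.79 ± 0.10) and MCM2 (−0.61 ± 0.09) fell, while CCNE2, a G1/S cyclin, rose by 1.15 ± 0.11. Of the 34 genes of G2 phase and mitosis 24 rose and 1 fell, 24 and 3 adjusted over the list alone (median 0.34, adjusted p = 1.5e-05, adjusted p = 0.0740 with an estimated correlation). Among them ECT2 changed by 0.91 ± 0.09, the mitotic kinase PLK1 by 0.88 ± 0.10 and CCNB1 by 0.40 ± 0.05. Nucleotide synthesis genes were lower in 12 of 23 and higher in 4, 13 and 4 adjusted over the list alone (median −0.27, adjusted p = 0.000807, adjusted p = 0.462 with an estimated correlation), a call that ended in 3 of 14 alternatives (adjusted p up to 0.336 at a mean of at least 4). PPAT, the first enzyme of purine synthesis, fell by 1.94 ± 0.13.

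NRF2 targets rose in 14 of 28 and fell in 2, 17 and 4 adjusted over the list alone (median 0.21, adjusted p = 0.00164, adjusted p = 0.279 with an estimated correlation). SLC7A11 rose by 2.35 ± 0.09, EPHX1, an epoxide hydrolase, by 1.71 ± 0.16, GCLM by 1.49 ± 0.09, NQO1 by 1.27 ± 0.09, SRXN1 by 0.98 ± 0.13 and TXNRD1 by 0.68 ± 0.07, while GCLC gave 0.07 ± 0.11 (adjusted p = 0.564). In the glutathione list 4 genes rose and 7 fell, 5 and 7 adjusted over the list alone, among them CBS (−1.09 ± 0.17). Its median of 0.05 and its test, which pointed down (adjusted p = 0.476), differed in sign, and the median was −0.00444 after quantile normalization. For transferases and pumps 2 rose and 3 fell (test down, adjusted p = 0.741, mean −0.11, median 0.05 as deposited and −0.01 after quantile normalization), with GSTA4 at −1.31 ± 0.16, the pump gene ABCC1 at −0.41 ± 0.10 and GSTP1 at −0.28 ± 0.13 (adjusted p = 0.0864). The thioredoxin and peroxiredoxin list had a median of −0.12 that turned to 0.05 after quantile normalization (4 rises, 5 falls, adjusted p = 0.198), and TXNIP fell by 1.01 ± 0.08.

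Of the 30 immediate early genes 17 rose and 3 fell, also adjusted over the list alone (median 0.62, adjusted p = 7.64e-05, adjusted p = 0.118 with an estimated correlation). JUN stood 3.08 ± 0.08 and FOS 1.22 ± 0.34 above vehicle. Rises within lists are to be read beside all 19775 genes, of which 4735 were called higher at 4 h, 3333 of them with a mean under 4. Of 23 NF-κB and inflammatory genes 11 rose and 2 fell, 13 and 2 adjusted over the list alone (median 0.14, adjusted p = 0.00811, adjusted p = 0.348 with an estimated correlation). Among them the monocyte chemoattractant CCL2 changed by 2.16 ± 0.07, CXCL2 by 2.08 ± 0.19 and PTGS2, the inducible cyclooxygenase, by 1.92 ± 0.26 from a level under 4. Monocyte and macrophage genes rose in 13 of 21 and fell in 1, with the same counts adjusted over the list alone (adjusted p = 0.000807, adjusted p = 0.109 with an estimated correlation). The median of these genes was 0.10 to 0.71 over 14 alternatives. In this group CD36 changed by 1.77 ± 0.08 and FCER1G, a signalling chain of Fc receptors, by 1.38 ± 0.07. Heat shock genes, with 8 rises and 3 falls, did not pass as a list (adjusted p = 0.253), although the cochaperones BAG3 (1.29 ± 0.14) and DNAJB1 (0.77 ± 0.10) rose. ATF4 targets, 7 higher and 13 lower, had a median of −0.08, a mean of 0.10 and a test that pointed down (adjusted p = 0.0866). In them PPP1R15A rose by 2.31 ± 0.16 and ASNS fell 2.84-fold. DDIT3 (0.12 ± 0.13, adjusted p = 0.438), TRIB3 (−0.09 ± 0.10, adjusted p = 0.485) and CHAC1 (−0.12 ± 0.07, adjusted p = 0.127), the last under the level of the trp probe sets, did not pass. CDKN1A rose by 3.42 ± 0.13, whereas the p53 list, with 4 rises and 5 falls, a median of −0.09 and a mean of 0.07, did not pass (adjusted p = 0.554). Among cell death genes PMAIP1 (1.27 ± 0.13), MCL1 (1.08 ± 0.07) and BCL2A1 (1.35 ± 0.05) rose and BCL2L11 (−1.22 ± 0.11) and BIK (−0.90 ± 0.18) fell, and neither the proapoptotic list (adjusted p = 0.579, median 0.06, mean −0.03) nor the antiapoptotic list (adjusted p = 0.102) passed.

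Called genes changed at least 2-fold numbered 270 higher and 552 lower at 4 h. Among genes with a mean of at least 4, a fit added after seeing the data, 1463 were higher and 3244 lower. Over all genes 4735 were higher and 3286 lower, but 3333 of the higher ones had a mean under 4, with a median rise of 0.09. The median difference of genes with a mean of at least 4 was −0.14 as deposited and −0.01 after quantile normalization, which gave 2289 higher and 2583 lower genes. For 70.2% of all genes the arrays did not overlap, against 10% by chance for a single gene. Small common shifts enter this share: genes with a mean under 4 lay a median of 0.0362 to 0.154 above the vehicle mean on the 4 h arrays. Of the 38 lists 15 were called, and 1 of these, cholesterol synthesis, holds with an estimated correlation. The count of higher genes was 1177, 1338 or 1121 without vehicle replicate 1, 2 or 3, 2477 without 4 h replicate 2 and 8147 without 4 h replicate 3, and the call of FOS ended without vehicle replicate 1 (adjusted p = 0.0559) or 2 (0.0662).

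The comparison of 24 h with vehicle covers the last time. C5AR1 rose at least 117-fold (6.87 ± 0.15), from a level of 3.09 ± 0.14, and TREM1, an amplifier of inflammation on myeloid cells, 49.9-fold (5.64 ± 0.21). MMP1 rose 101-fold, from 5.48 ± 0.25 to 12.14 ± 0.06 (SD, n = 3). Ribosome biogenesis genes fell in 29 of 29 measured, and genes of the G1/S transition and replication in 30 of 31, while 31 of 34 genes of G2 phase and mitosis rose. MYC fell 19.8-fold to a level of 8.18 ± 0.06, and CDKN1A rose by 5.54 ± 0.13. The 24 h arrays held poly-A spikes (8.47, against 3.04 in vehicle), and their hybridization spikes (11.70 against 9.96) and 28S probe sets (11.19 against 9.04) were higher.

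The largest rises were EMP1 (8.25 ± 0.24), C5AR1, MMP1, IER3 (6.16 ± 0.22), GPR34 (5.91 ± 0.21), a lysophosphatidylserine receptor, FPR1 (5.80 ± 0.33), the formyl peptide receptor of phagocytes, TREM1 and TDO2 (5.55 ± 0.08), which starts the breakdown of tryptophan. All but MMP1 and TREM1 rose from levels under 4. Those of IER3 (2.65), FPR1 (2.30) and TDO2 (2.23) were near or under that of the trp probe sets (2.53), and the order of these 6 rises is not exact. The largest falls were PLAC8 (−4.85 ± 0.35), MARS2 (−4.63 ± 0.21), FAM161A (−4.55 ± 0.16), MS4A3 (−4.42 ± 0.09), a gene of granulocyte-monocyte progenitors, PUS7 (−4.32 ± 0.17), a pseudouridine synthase, MYC (−4.31 ± 0.08), FERMT1 (−4.25 ± 0.24) and MCM10 (−4.04 ± 0.31), a replication initiation factor. MARS2, FAM161A and FERMT1 fell to levels under 4, FAM161A to one (2.49) under that of the trp probe sets (2.63 at 24 h).

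Ribosome biogenesis genes had a median of −1.64, with 29 lower also adjusted over the list alone (adjusted p = 2.63e-27, adjusted p = 0.0740 with an estimated correlation). Among them were UTP20 (−2.99 ± 0.23, to a level under 4), POLR1B (−2.69 ± 0.09), POLR1C (−2.63 ± 0.16) and WDR74 (−2.50 ± 0.13). Genes of the G1/S transition and replication had a median of −1.28, with 30 lower adjusted over the list alone (adjusted p = 1.71e-24, adjusted p = 0.0745 with an estimated correlation). Besides MCM10, the licensing factor CDC6 (−3.54 ± 0.14), the cyclin CCNE1 (−3.19 ± 0.35), GINS2 (−2.86 ± 0.09) and MCM2 (−2.35 ± 0.09) fell. In G2 phase and mitosis the median was 1.14, with 31 genes higher and 1, BUB3, lower, also adjusted over the list alone (adjusted p = 6.24e-16, adjusted p = 0.0111 with an estimated correlation). PLK1 rose by 2.03 ± 0.10, the kinetochore motor CENPE by 1.85 ± 0.09, HMMR by 1.80 ± 0.09, the kinase NEK2 by 1.79 ± 0.07 and CCNB1 by 1.13 ± 0.05. Nucleotide synthesis genes were lower in 18 of 23 and higher in 1, 18 and 3 adjusted over the list alone (median −1.17, adjusted p = 2.93e-10, adjusted p = 0.196 with an estimated correlation). Among them PPAT changed by −3.14 ± 0.13, PFAS by −2.40 ± 0.11 and PAICS by −2.22 ± 0.07, all of purine synthesis, and DHODH by −3.12 ± 0.21. Of 15 genes of homologous recombination 12 fell, also adjusted over the list alone (median −0.70, adjusted p = 3.41e-07, adjusted p = 0.0740 with an estimated correlation). EXO1 fell by 2.35 ± 0.10.

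**Figure D3:**
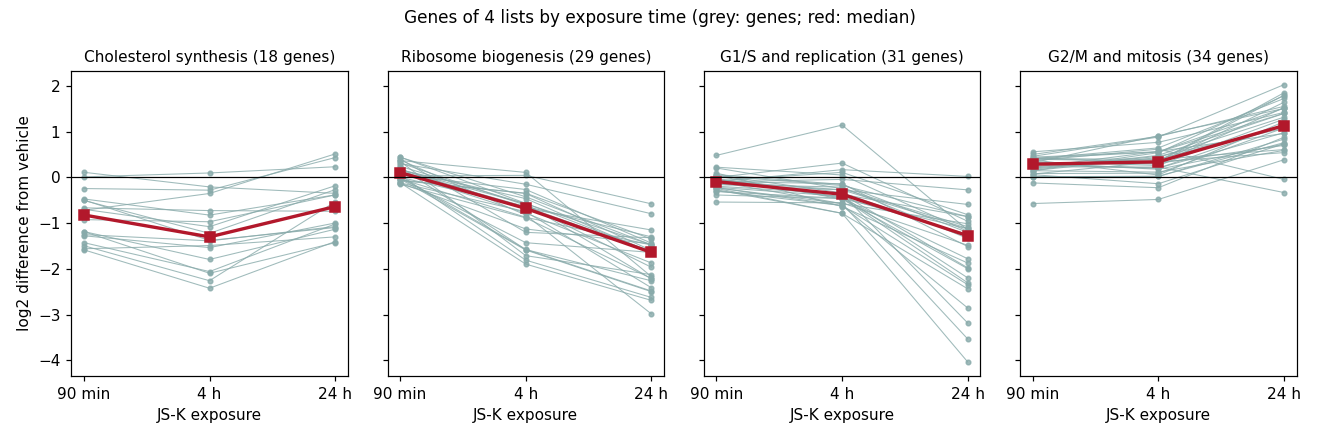
Log2 difference from vehicle (y axis) at 90 min, 4 h and 24 h (x axis) for the genes of 4 lists, with a grey line per gene and the list median in red. The medians reach −1.30 for cholesterol synthesis at 4 h, and −1.64 for ribosome biogenesis, −1.28 for G1/S and 1.14 for G2/M at 24 h.

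Proteasome subunits fell in 24 of 27, with 24 lower and 1 higher adjusted over the list alone (median −0.38, adjusted p = 7.42e-10, adjusted p = 0.321 with an estimated correlation). In this group PSMD1 fell by 1.36 ± 0.11. Oxidative phosphorylation genes fell in 28 of 42 and rose in 1, 29 and 1 adjusted over the list alone (median −0.31, adjusted p = 2.7e-10, adjusted p = 0.321 with an estimated correlation). Among them were the complex I subunits NDUFA10 (−1.22 ± 0.11) and NDUFA8 (−1.20 ± 0.11) and the cytochrome gene CYC1 (−0.97 ± 0.11). Citric acid cycle genes fell in 15 of 21 and rose in 3, 16 and 3 adjusted over the list alone (median −0.53, adjusted p = 5.26e-07, adjusted p = 0.132 with an estimated correlation). Members that fell included IDH3A (−1.12 ± 0.07) and PDHA1 (−1.03 ± 0.06). Glycolysis genes, 5 higher and 6 lower, did not pass as a list (adjusted p = 0.233). Pentose phosphate and NADPH genes fell in 11 of 17 and rose in 3, 11 and 4 adjusted over the list alone (median −0.44, adjusted p = 0.000807, adjusted p = 0.118 with an estimated correlation). Among them MTHFD1 changed by −1.45 ± 0.06 and RPIA by −1.37 ± 0.08. Cholesterol synthesis genes were still below vehicle, 14 of 18 lower and 2 higher, 14 and 3 adjusted over the list alone (median −0.64, adjusted p = 1.96e-06, adjusted p = 0.0743 with an estimated correlation). Among them INSIG1 changed by −1.43 ± 0.08, HMGCS1 by −1.40 ± 0.11, DHCR7 by −1.30 ± 0.10 and IDI1 by −1.13 ± 0.08.

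Redox genes were again divided. The 28 NRF2 targets held 11 rises and 6 falls, 15 and 6 adjusted over the list alone, and did not pass as a list (median 0.11, adjusted p = 0.421). HMOX1 rose by 1.76 ± 0.30 from a level under 4, NQO1 by 1.51 ± 0.09, SLC7A11 by 1.27 ± 0.09 and SRXN1 by 0.80 ± 0.13, while GCLC fell by 1.62 ± 0.11, and GCLM (0.11 ± 0.09, adjusted p = 0.308) and TXNRD1 (0.10 ± 0.07, adjusted p = 0.246) did not pass. In the glutathione list 4 rose and 8 fell (median −0.08, adjusted p = 0.0857), with CBS at −1.88 ± 0.17, CTH at −1.74 ± 0.12 and HAGH, a glyoxalase, at 1.60 ± 0.13. Among transferases and pumps 3 rose and 4 fell (adjusted p = 0.928), GSTO1 by 0.60 ± 0.07, MGST1 by −0.59 ± 0.06 and GSTP1 by −0.46 ± 0.13, and the list median of 0.06 was −0.00234 after quantile normalization and −0.01 with array medians subtracted. Thioredoxin and peroxiredoxin genes fell in 8 of 19 and rose in 3, also adjusted over the list alone (median −0.24, adjusted p = 0.0150, adjusted p = 0.558 with an estimated correlation), a call that ended in 5 of 15 alternatives (adjusted p up to 0.439 at a mean of at least 4). Among them the peroxiredoxins PRDX6 changed by −1.05 ± 0.09 and PRDX1 by −0.90 ± 0.08, whereas TXNIP rose by 1.58 ± 0.08. Endoplasmic reticulum chaperones, higher at 90 min, were lower at 24 h in 11 of 21 and higher in 2, 11 and 3 adjusted over the list alone (median −0.41, adjusted p = 0.000362, adjusted p = 0.306 with an estimated correlation). In this group SDF2L1 changed by −1.54 ± 0.20 and DNAJB9 by −1.49 ± 0.12. Heat shock genes fell in 7 of 22 and rose in 4, 8 and 4 adjusted over the list alone (adjusted p = 0.0409, adjusted p = 0.433 with an estimated correlation), a call that ended in 6 of 15 alternatives (adjusted p up to 0.413 at a mean of at least 4, and 0.0561 without vehicle replicate 1). HSPA4L (−2.85 ± 0.22) and FKBP4 (−1.74 ± 0.12) fell and BAG3 (1.69 ± 0.14) and HSPA6 (1.56 ± 0.21) rose, while DNAJB1 gave 0.10 ± 0.10 (adjusted p = 0.373).

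ATF4 targets fell in 20 of 34 and rose in 7, also adjusted over the list alone (median −0.33, adjusted p = 5.87e-05, adjusted p = 0.348 with an estimated correlation). Among them the serine synthesis enzyme PSAT1 changed by −2.09 ± 0.07 and ASNS by −1.93 ± 0.25 but ATF3 by 4.97 ± 0.20 and PPP1R15A by 2.65 ± 0.16. TRIB3 fell by 0.31 ± 0.10. DDIT3 (−0.21 ± 0.13, adjusted p = 0.183) and CHAC1 (−0.11 ± 0.07, adjusted p = 0.172), the latter under the level of the trp probe sets, did not pass. Inflammatory NF-κB genes rose in 15 of 23 and fell in 1, 16 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.000299, adjusted p = 0.211 with an estimated correlation). In this group CXCL8 changed by 4.73 ± 0.06, CCL2 by 4.26 ± 0.07 and the interleukin gene IL1B by 2.83 ± 0.16 from a level under 4. JUN stood at 3.14 ± 0.08 and FOS at 1.10 ± 0.34 above vehicle, within an immediate early list of 12 rises and 4 falls, 15 and 5 adjusted over the list alone (median 0.24, adjusted p = 0.0178, adjusted p = 0.321 with an estimated correlation), whose call ended without 4 h replicate 2 (adjusted p = 0.0980). Monocyte and macrophage genes rose in 14 of 21 and fell in 1, 15 and 1 adjusted over the list alone (median 0.53, adjusted p = 7.5e-06, adjusted p = 0.0676 with an estimated correlation). Among them the costimulatory CD86 changed by at least 4.73 ± 0.14 from a level (2.12) under that of the trp probe sets and FCER1G by 2.77 ± 0.07. Myeloid progenitor genes fell in 8 of 15 and rose in 3, also adjusted over the list alone (median −0.30, adjusted p = 0.0409, adjusted p = 0.413 with an estimated correlation). Among them MYB changed by −2.06 ± 0.09 and GFI1 by −1.81 ± 0.12 but SPI1 by 1.58 ± 0.19. Autophagy and lysosome genes rose in 12 of 22 and fell in 1, 13 and 1 adjusted over the list alone (median 0.34, adjusted p = 0.0251, adjusted p = 0.497 with an estimated correlation). The protease gene CTSB rose by 1.73 ± 0.07, and the list call ended without 4 h replicate 2 (adjusted p = 0.0842). Cell death genes moved both ways: BMF (2.33 ± 0.20), PMAIP1 (1.59 ± 0.13) and MCL1 (1.33 ± 0.07) rose and BCL2L11 (−1.90 ± 0.11) and DIABLO (−1.20 ± 0.08) fell, and the proapoptotic (adjusted p = 0.681), antiapoptotic (adjusted p = 0.127) and p53 (adjusted p = 0.416) lists did not pass.

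At 24 h 914 called genes were at least 2-fold higher and 1402 at least 2-fold lower. With no minimum fold, 3518 genes were higher and 3735 lower, of which 1044 of the higher had a mean under 4, and among genes with a mean of at least 4 the counts were 2669 and 3750. For 82.3% of all genes the arrays did not overlap, against 10% by chance for a single gene. Small common shifts enter this share too: genes with a mean under 4 lay a median of 0.0571 to 0.0684 above the vehicle mean on the 24 h arrays. Of the 38 lists 20 were called, and 1 of these, G2 phase and mitosis, holds with an estimated correlation. With the preset correlation, 3 of 15 alternatives ended the calls of autophagy (adjusted p up to 0.175) and myeloid progenitor genes (0.161) and 2 that of immediate early genes (0.216). A mean of at least 4 ended those of ATF4 targets (0.0511), endoplasmic reticulum chaperones (0.119) and pentose phosphate genes (0.0537). The count of higher genes was 10291 without 4 h replicate 2, of which 7418 had a mean under 4. Without vehicle replicate 1 or 3, 336 or 378 genes with a mean under 4 were called higher. The call of FOS ended without vehicle replicate 1 (adjusted p = 0.0596) or 2 (0.0883) or 24 h replicate 1 (0.0675), that of GSTP1 without vehicle replicate 2 (0.0680) or 24 h replicate 3 (0.0560), and that of TRIB3 without vehicle replicate 1 (0.0765), 2 (0.0751) or 3 (0.0653) or 24 h replicate 1 (0.0515), 2 (0.0660) or 3 (0.0955).

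The comparison of 4 h with 90 min tests the change between the first and the middle time directly. Ribosome biogenesis genes fell in 27 of 29, also adjusted over the list alone (median −0.86, adjusted p = 1.16e-32, adjusted p = 0.0676 with an estimated correlation). Among them RRS1 changed by −2.06 ± 0.12, POLR1C by −1.87 ± 0.16 and WDR43 by −1.80 ± 0.28. The largest falls of single genes were MARS2 (−3.51 ± 0.21), TWNK (−3.27 ± 0.38), URB2 (−2.18 ± 0.17) and BYSL (−2.09 ± 0.33), the last of them a gene of small ribosomal subunit assembly, and FOS (−2.07 ± 0.34). PALLD (2.70 ± 0.13), an actin-associated protein gene, KYNU (2.66 ± 0.08), kynureninase, HMOX1 (2.57 ± 0.30), MAML2 (2.52 ± 0.21) and DAAM1 (2.48 ± 0.12) rose most. The 4 h arrays held poly-A spikes (7.02) that the 90 min arrays lacked (3.08).

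Cholesterol synthesis genes fell further between these times, 8 of 18, or 11 with 1 rise adjusted over the list alone (median −0.34, adjusted p = 8.98e-08, adjusted p = 0.0676 with an estimated correlation). Among them INSIG1 changed by −0.91 ± 0.08. Nucleotide synthesis genes fell in 9 of 23 and rose in 1, 13 and 2 adjusted over the list alone (median −0.29, adjusted p = 1.94e-06, adjusted p = 0.321 with an estimated correlation), and replication genes in 11 of 31 with 2 rises, 15 and 3 adjusted over the list alone (median −0.21, adjusted p = 2.23e-06, adjusted p = 0.377 with an estimated correlation). Endoplasmic reticulum chaperones fell in 5 of 21, or 7 with 1 rise adjusted over the list alone (median −0.12, adjusted p = 0.000362, adjusted p = 0.306 with an estimated correlation). In this group SDF2L1 fell by 1.08 ± 0.20. Among redox genes SLC7A11 (1.63 ± 0.09), GCLM (0.81 ± 0.09) and TXNRD1 (0.40 ± 0.07) rose, and NRF2 targets rose in 8 of 28, or 11 adjusted over the list alone (median 0.14, adjusted p = 0.0240, adjusted p = 0.402 with an estimated correlation), a call that ended without 4 h replicate 1 (adjusted p = 0.107) or 3 (0.127). CDKN1A rose by 1.92 ± 0.13 and MYC fell by 1.30 ± 0.08, while the genes of G2 phase and mitosis did not pass as a list (adjusted p = 0.473; median 0.04, and −0.02 with array medians subtracted). ATF3 (0.71 ± 0.20), NQO1 (0.31 ± 0.09), JUN (−0.30 ± 0.08), MCM2 (−0.32 ± 0.09) and DNAJB1 (0.44 ± 0.10) were called too. These calls ended without any 1 of the 6 arrays other than 4 h replicate 2 for ATF3 (adjusted p = 0.0578 to 0.149) and NQO1 (0.0501 to 0.123), other than 90 min replicate 3 for JUN (0.0537 to 0.175) and other than 4 h replicate 1 for MCM2 (0.0537 to 0.159), and without 90 min replicate 3 for DNAJB1 (0.0504). For SRXN1 the difference was 0.43 ± 0.13 (adjusted p = 0.0554) and for TRIB3 0.31 ± 0.10 (0.0833), and GCLC (0.168), GSTP1 (0.897), DDIT3 (0.591), CHAC1 (0.402) and CCNB1 (0.830) had higher adjusted p values. In all 658 genes were higher and 1434 lower, 111 and 178 of them at least 2-fold, and 51.7% of genes did not overlap (10% by chance). Quantile normalization gave 1083 and 1250, and subtraction of array medians 374 and 1160. Of the 38 lists 14 were called, of which 8 were also called by fry and none holds with an estimated correlation, where the lowest adjusted p was 0.0676. Oxidative phosphorylation was among the 14, and its median was −0.04 as deposited and 0.04 after quantile normalization. Its call (adjusted p = 0.0266) ended in 7 of 14 alternatives (adjusted p up to 0.878), among them those without 4 h replicate 2 (0.876) and 90 min replicate 1 (0.0604). The calls of NRF2 targets, endoplasmic reticulum chaperones and replication genes ended in 4, 2 (up to 0.257) and 1 (0.0762) of 14. The count of lower genes was 921 without 90 min replicate 1 and 915 without 90 min replicate 3.

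The comparison of 24 h with 4 h tests the later change directly, on arrays that both held poly-A spikes (8.47 and 7.02) but differed in hybridization spikes (11.70 and 10.21). Replication genes fell in 30 of 31 and genes of G2 phase and mitosis rose in 30 of 34 with 2 falls. The largest rises were TDO2 (5.35 ± 0.08), GPR34 (5.05 ± 0.21), CD86 (4.68 ± 0.14), ATP6V0D2 (4.39 ± 0.18), a subunit of the proton pump of acidic compartments, and PSD3 (4.20 ± 0.17), of which all but PSD3 rose from levels under 4. Those of TDO2 (2.43), CD86 (2.16) and ATP6V0D2 (2.31) were under that of the trp probe sets (2.66 at 4 h), and the order of these 4 rises is not exact. MS4A3 (−4.72 ± 0.09), PLAC8 (−4.15 ± 0.35), IPO4 (−3.77 ± 0.13), a nuclear import receptor gene, SLC29A1 (−3.60 ± 0.16), a nucleoside transporter, and PUS7 (−3.59 ± 0.17) fell most. Between these times HMOX1 (−3.22 ± 0.30), GCLC (−1.69 ± 0.11), GCLM (−1.38 ± 0.09) and SLC7A11 (−1.08 ± 0.09) fell, and CDKN1A (2.12 ± 0.13) and TXNIP (2.60 ± 0.08) rose. TXNRD1 (−0.58 ± 0.07), DNAJB1 (−0.67 ± 0.10), MYC (−1.52 ± 0.08) and MCM2 (−1.73 ± 0.09) also fell, and ATF3 (1.04 ± 0.20) and CCNB1 (0.73 ± 0.05) rose. NQO1 gave 0.25 ± 0.09 (adjusted p = 0.0686) and DDIT3 −0.33 ± 0.13 (0.0990), and adjusted p values were 0.161 for TRIB3, 0.471 for SRXN1, 0.505 for GSTP1, 0.778 for JUN, 0.871 for FOS and 0.927 for CHAC1.

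The replication list had a median of −1.23 (30 lower also adjusted over the list alone, adjusted p = 1.4e-27, adjusted p = 0.0740 with an estimated correlation) and the list of G2 phase and mitosis one of 0.86 (31 higher and 2 lower adjusted over the list alone, adjusted p = 9.17e-24, adjusted p = 0.00654 with an estimated correlation). CDC6 fell by 2.96 ± 0.14 and CCNE2 by 2.30 ± 0.11, and HMMR rose by 1.46 ± 0.09 and BIRC5, survivin, by 1.32 ± 0.11. Ribosome biogenesis genes fell in 25 of 29, or 26 adjusted over the list alone (median −0.91, adjusted p = 1.06e-21, adjusted p = 0.105 with an estimated correlation). In this group MYBBP1A fell by 2.28 ± 0.14. Cholesterol synthesis genes turned and rose in 12 of 18, also adjusted over the list alone (median 0.62, adjusted p = 1.59e-09, adjusted p = 0.0487 with an estimated correlation). In this group MSMO1 changed by 1.73 ± 0.06 and HMGCS1 by 1.02 ± 0.11. Heat shock genes fell in 14 of 22 and rose in 1, also adjusted over the list alone (median −0.37, adjusted p = 2.63e-06, adjusted p = 0.105 with an estimated correlation), and endoplasmic reticulum chaperones in 15 of 21 with 2 rises, also adjusted over the list alone (median −0.59, adjusted p = 6.84e-08, adjusted p = 0.118 with an estimated correlation). Among them HSPA5, the main chaperone of that compartment, changed by −1.12 ± 0.05. In the p53 list 7 of 20 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.19, adjusted p = 0.00241, adjusted p = 0.0740 with an estimated correlation). In this group RRM2B changed by 1.15 ± 0.07 and TIGAR by 0.94 ± 0.08. NRF2 targets fell in 11 of 28 and rose in 3, also adjusted over the list alone (median −0.14, adjusted p = 0.00804, adjusted p = 0.323 with an estimated correlation), a call that ended without 4 h replicate 1 (adjusted p = 0.0636) and with array medians subtracted (0.102). Between 4 h and 24 h 2535 genes were higher and 2114 lower, 550 and 528 of them at least 2-fold, and 28.4% of genes did not overlap (10% by chance). With array medians subtracted the counts were 2160 and 4438. Of the 38 lists 21 were called, and 2 of these hold with an estimated correlation (G2 phase and mitosis, cholesterol synthesis).

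**Figure D4:**
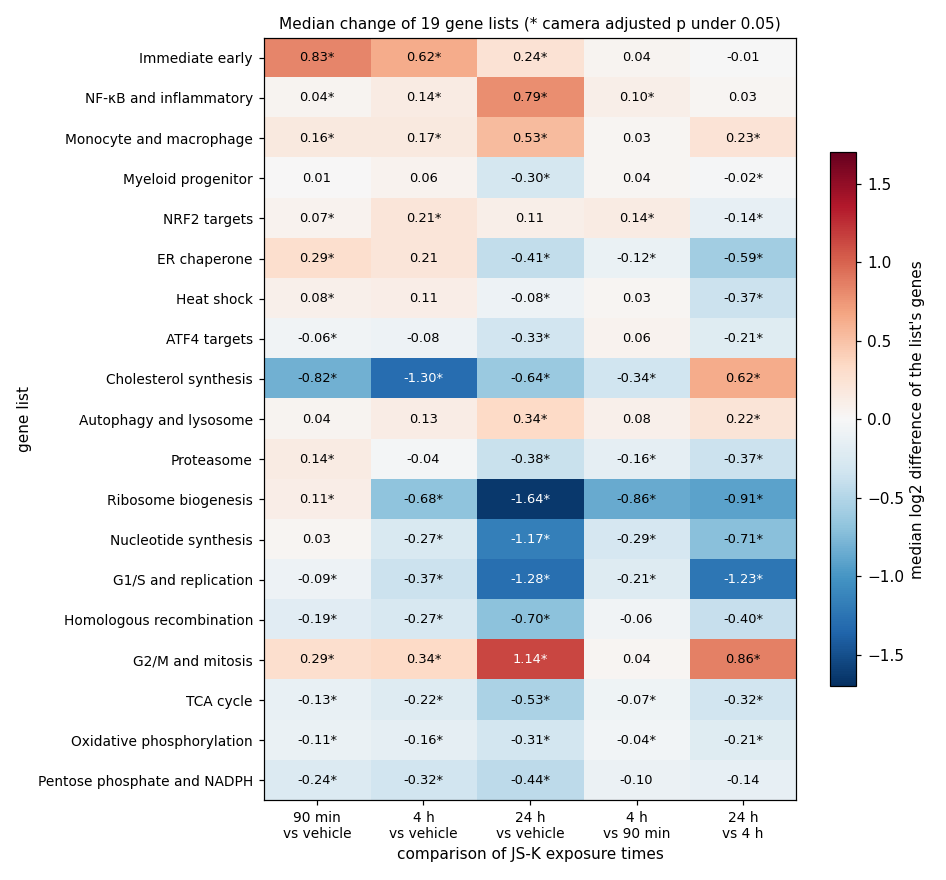
Median log2 difference (colour) of 19 gene lists in the 5 comparisons, with a star where the camera adjusted p is under 0.05. Ribosome biogenesis goes from 0.11 at 90 min to −1.64 at 24 h, and medians near 0 can change sign with scaling, as for the proteasome at 4 h (−0.04 as deposited, 0.03 after quantile normalization) and oxidative phosphorylation at 4 h against 90 min (−0.04, 0.04).

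Over the whole design 7543 genes differed among the 4 groups by the F test, and this count was 13200 without 4 h replicate 2 and 11491 without 4 h replicate 3. At all 3 times 473 genes were higher than in vehicle and 727 lower. Of the genes higher at 4 h, 600 were higher again at 24 h than at 4 h and 260 were lower, and of those lower at 4 h, 947 were lower again and 620 higher. Between 90 min and 24 h 512 higher and 752 lower genes were shared, against 142 and 210 for independent lists, and 131 genes went from higher to lower and 131 from lower to higher. Between 90 min and 4 h 594 and 958 were shared (191 and 185 for independent lists), and between 4 h and 24 h 1543 and 2417 (842 and 621). Unchanged groups that shared the vehicle arrays gave at most 1 shared gene in 20 simulations. These drew each gene on its own, without a shift common to an array. They therefore cannot tell a shared response from a shared shift of the arrays. Differences from vehicle correlated across genes at 0.730 between 90 min and 4 h, 0.436 between 90 min and 24 h and 0.728 between 4 h and 24 h. The simulations gave 0.506, 0.503 and 0.502, where the shared vehicle arrays alone link the differences. That simulated value is set by the sharing and is no baseline for genes that change. The covariances were 0.0937, 0.0884 and 0.222, against 0.00838, 0.00829 and 0.00830 in the simulations.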

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

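The tests of a single array, of the preparation as the whole cause, of the hybridization spikes, of 28S and 18S RNA and of RNA45SN5 were chosen only after the result was seen, as were the gene RNA45SN5 itself and the counts of dim genes, also at the other times.

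Of the 4735 genes called higher at 4 h than in vehicle, 3333 had a mean under 4, their median rise was 0.09 and 7 of them reached 2-fold. Of all 10224 genes with a mean under 4, 91.6% had a positive difference at 4 h, where 70% or fewer would have counted against a common upward shift of the low end. That shift stays open as the cause, because the share was 84.3% at 90 min and 92.1% at 24 h too, where 27 and 1044 of these genes were called higher. Without 4 h replicate 2, whose low end was raised, 966 of these genes were called, but the count also went to 73, 250 and 77 without vehicle replicate 1, 2 and 3, to 377, 557 and 3123 without 90 min replicate 1, 2 and 3 and to 393, 370 and 398 without 24 h replicate 1, 2 and 3, and it rose to 5137 and 6813 without 4 h replicate 1 and 3. Since 8 of the other 11 arrays lowered the count by more when left out, what that array contributes cannot be told apart from the effect of fewer arrays in the fit. The count at 24 h was not stable either, at 7418 without 4 h replicate 2 and 336 without vehicle replicate 1. At 90 min it was 14 to 52 when 1 array was left out, so the comparison of shares rests on 90 min. The trp probe sets were 0.13 higher at 4 h than in vehicle (2.66 ± 0.12 and 2.53 ± 0.02, SD, n = 3). A rise of the size of the median (0.09) thus also occurred where no spike was added. A change of the dim genes by JS-K stays open and was not tested.

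At 24 h the lists of G1/S and replication, of ribosome biogenesis and of G2 phase and mitosis had medians of −1.28, −1.64 and 1.14 against vehicle, on arrays with poly-A spikes that the vehicle arrays lack. A level-dependent change of signal is argued against, since the medians of 24 h against 4 h (−1.23, −0.91 and 0.86) lay at percentiles 0, 0 and 100 of 10000 lists matched on level. In the test of 24 h against 4 h, the preparation that these spikes mark cannot be told apart from exposure time as the whole cause of each shift, because the spikes also differ by 1.45 between these arrays. Another difference in hybridization or handling of the 24 h arrays cannot be told apart from it either, because their hybridization spikes were 1.49 above those of the 4 h arrays and the 3' minus 5' difference of GAPDH (0.114 to 0.141) was the highest of the series. G2 phase and mitosis genes also rose at 90 min (medians 0.20 to 0.32 over 15 alternatives, camera adjusted p up to 8.31e-06). Poly-A spikes (3.08, and 3.04 in vehicle) and hybridization spikes (10.03 and 9.96) were alike there. This argues against the preparation that the poly-A spikes mark as the cause of that early rise, but not of the size at 24 h. Control probe sets for 18S ribosomal RNA averaged 7.06 ± 0.91 at 90 min and 9.78 ± 1.69 in vehicle (SD, n = 3). Other differences in preparation therefore stay open at 90 min. At 90 min the ribosome biogenesis median was 0.11, and the G1/S call ended in 7 of 15 alternatives. A response of the cell cycle and of ribosome production to JS-K stays open, as does time in culture.

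RNA45SN5, the precursor of the large ribosomal RNAs, was 3.55 higher at 24 h than in vehicle (10.22 ± 0.12 against 6.66 ± 0.21, SD, n = 3) while ribosome biogenesis genes had a median of −1.64. The control probe sets for mature 28S RNA were 2.15 higher too, but those for 18S RNA (9.78 ± 1.69 in vehicle and 10.52 ± 0.96 at 24 h) differed by 0.73, which is within their spread. More ribosomal RNA of every kind in the labelled material and a change by JS-K in its synthesis or processing cannot be told apart, because no arrays prepared and hybridized alike differ in exposure time by this much. The other probe set of RNA45SN5 was at 5.47 ± 0.28 in vehicle and 9.07 ± 0.13 at 24 h, and these 2 probe sets were at 5.73 ± 0.46 and 5.16 ± 0.10 at 90 min and at 6.28 ± 0.53 and 5.49 ± 1.02 at 4 h.

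Several results differed between exposure times in a direct test of the difference. The median of the ribosome biogenesis list was 0.11 at 90 min and −0.68 at 4 h (median of the differences −0.86, adjusted p = 1.0e-32 over 228 tests, adjusted p = 0.0696 with an estimated correlation), and −1.64 at 24 h (−1.92 from 90 min, with the same adjusted p values). MS4A3 was 0.38 from vehicle at 90 min, 0.29 at 4 h and −4.42 at 24 h, which is −4.80 from 90 min to 24 h and −4.72 from 4 h to 24 h. IPO4 was 0.64 from vehicle at 90 min and −3.48 at 24 h, a difference of −4.12. The heat shock list had medians of 0.08 at 90 min and −0.08 at 24 h (median of the differences −0.31, adjusted p = 0.000337, adjusted p = 0.195 with an estimated correlation). The list of endoplasmic reticulum chaperones had medians of 0.29 and −0.41 at these times (−0.61, adjusted p = 4.11e-10, adjusted p = 0.0840 with an estimated correlation). The proteasome list had medians of 0.14 and −0.38 (−0.52, adjusted p = 3.73e-15, adjusted p = 0.198 with an estimated correlation). Against vehicle, the calls of ribosome biogenesis, heat shock and proteasome at 90 min ended in 4, 2 and 1 of 15 alternatives, and those of heat shock and of the chaperones at 24 h in 6 and 1.

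Some signal lay outside the genes compared. The poly-A spike probe sets averaged 7.02 at 4 h and 8.47 at 24 h, against 3.04 in vehicle. Of 11721 probe sets without a listed gene and outside the controls, 40 were called higher and at least 2-fold at 90 min, 66 at 4 h and 159 at 24 h. With 3 arrays per group, single arrays far from the rest of their group were not tested.

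Other groupings of the same arrays were fitted. The 6 arrays of a comparison have 10 splits, too few for a share under 0.05, and in each comparison only the real split, 1 of 10, gave as many genes. The real split called 2508 genes for 90 min, 3185 for 4 h and 14569 for 24 h against vehicle, 1227 for 4 h against 90 min and 3694 for 24 h against 4 h, and the highest other split called 0 each time. For the F test over 12 arrays 2 of 100 splits, the real one included, called at least 7543 genes, so chance can be excluded at that share. The highest other split, with 8182 genes, kept the vehicle arrays together and the 90 min arrays together and mixed the 4 h with the 24 h arrays. It thus kept the division of the arrays by poly-A spikes. The count of the F test therefore cannot tell exposure time from preparation.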

How the results depend on the processing

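The count at 2-fold, the fit of genes with a mean of at least 4 and, for 90 min and 24 h against vehicle, the fit without JS-K 4 h replicate 2 were chosen only after the data were seen. Signal over background limits the counts: 51.7% of genes have a mean under 4, and they are 3333 of the 4735 higher calls at 4 h and 1044 of 3518 at 24 h. Without 4 h replicate 2 they were 966 at 4 h and 7418 of 10291 at 24 h. Counts are given as higher/lower in the order 90 min, 4 h and 24 h against vehicle, 4 h against 90 min and 24 h against 4 h, and the cause was not tested except where fewer genes or arrays entered. With every probe set tested, and so with more tests, the F test called 14886 and the counts were 1273/1785, 7711/5941, 6932/7843, 1059/2208 and 4235/3973. Array weights, whose estimate did not converge (29.0 and 0.0413 for 4 h replicates 1 and 2), gave 17984 for the F test, 6207/3320 at 90 min, 11257 higher at 4 h, 11458 higher at 24 h, 7193/3272 and 4149/3749. Against a fold of 1.5 the counts were 74/60, 224/324, 951/1408, 59/69 and 477/497, and at 2-fold 120/156, 270/552, 914/1402, 111/178 and 550/528. The 6 arrays alone gave 1018/2167 at 4 h, 10514 higher at 24 h and 385/842 for 4 h against 90 min. Quantile normalization gave 2289 higher at 4 h and 1083 higher for 4 h against 90 min. Subtracted medians gave 622 lower at 90 min, 374 higher for 4 h against 90 min and 4438 lower for 24 h against 4 h. Higher counts at 4 h were 1507 without a trend, 1741 without the dimmest genes and 1463 at a mean of at least 4, and without 4 h replicate 2 the higher count at 24 h was 10291. The labels do not say whether arrays of equal number belong together: 7 of 18 such pairs had residual correlations over 0.1 (at most 0.369), and 8 of 12 arrays correlated best with one of their own number, a hint from the data and not the design. The block by number gave 8539 for the F test, 819/1124, 6591/3493, 4232/3786, 703/1497 and 2561/2146. Leaving out 1 array of the groups compared, or 4 h replicate 2 for 90 min and 24 h against vehicle, gave 6700 to 13200 for the F test, 549 to 1063 and 631 to 1549 at 90 min, 1121 to 8147 and 2302 to 3782 at 4 h, 2575 to 10291 and 3300 to 4214 at 24 h, 461 to 785 and 915 to 1825 for 4 h against 90 min, and 2135 to 2654 and 1801 to 2619 for 24 h against 4 h. Lists called then numbered 16 to 18, 15 to 17, 19 to 21, 11 to 15 and 17 to 24, with an estimated correlation 4, 1, 1, 0 and 2, and with fry 24 at 4 h and 31 at 24 h.

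Only called results can lose a call. Of 695 results for named genes 664 were called, of which 113 lost their call without at least 1 array and 354 against a fold of 1.5. Of 190 list results, 18, 15, 20, 14 and 21 were called in the 5 comparisons, in the order above. Of these called results, 80 were lost with an estimated correlation, 20 without at least 1 array and 17 with subtracted medians. Without the dimmest genes 16 were lost, with quantile normalization 13, with fry 12 and with array weights 11. The mean of probe sets ended 7, a fit without a trend 5 and the block 3. At a mean of at least 4, where 170 list results could be run, 27 calls were lost. A direction reversed for ATP6V1H (−0.0769) and MCL1 (−0.0993) at 24 h against 4 h and RPL18 (0.0114) at 4 h with the mean of probe sets, for GSTP1 (0.24) at 4 h against 90 min with array weights, for H4C4 (−0.00387) at 4 h with quantile normalization, for the test of the glutathione (median 0.0521) and p53 (−0.0918) lists at 4 h with fry, for the immediate early list (0.0470) at a mean of at least 4, and for the oxidative phosphorylation list with quantile normalization (0.0384) and at a mean of at least 4 (−0.0442), the last 3 at 4 h against 90 min. At a mean of at least 4 the T cell, B cell, erythroid and epithelial lists were not run, since fewer than 3 of their genes were left. Every probe set was not run for lists, nor the fold of 1.5 for the F test.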

Other observations

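The 4 gene groups tested as hypotheses in this part were chosen after the largest changes had been seen, without the members first seen, and the test of each was fixed before its values were computed, except that the tests among genes with a mean of at least 4 were added after the results were seen.

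Genes of the response to interferon and of nitric oxide handling moved at 24 h without their lists passing the test. Of 25 interferon genes 8 rose and 2 fell, also adjusted over the list alone (median 0.09, adjusted p = 0.118), with the antiviral enzyme OAS1 at 3.31 ± 0.14 from a level under 4, the transcription factor IRF9 at 2.54 ± 0.26, IFIT3 at 2.09 ± 0.24 and IRF7 at 1.54 ± 0.13 (log2 difference ± SE, n = 3 and 3). Between 4 h and 24 h the list did rise, with 6 rises and 1 fall, also adjusted over the list alone (adjusted p = 0.00816, adjusted p = 0.259 with an estimated correlation). Of 16 genes of nitric oxide metabolism 5 rose and 3 fell, 8 and 3 adjusted over the list alone (adjusted p = 0.233). The arginase ARG2 rose by 3.71 ± 0.28, DDAH2, which breaks down inhibitors of nitric oxide synthases, by 3.37 ± 0.21 and GCH1, the first enzyme of tetrahydrobiopterin synthesis, by 1.84 ± 0.31, and ASS1, argininosuccinate synthase, fell by 1.56 ± 0.08. Among hypoxia genes, 4 higher and 5 lower (adjusted p = 0.710), HILPDA fell by 2.49 ± 0.20 and NDRG1 and DDIT4 rose by 1.61 ± 0.12 and 1.08 ± 0.09.

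Among markers of other cell types, T cell genes gave small differences, most of them at low signal. All genes with a mean under 4 lay a median of 0.0362 to 0.154 above the vehicle mean on the 4 h arrays. The median of the T cell list at 4 h lies within that range. Of 14 T cell markers 7 were called higher at 4 h, 9 adjusted over the list alone (median 0.08, adjusted p = 0.0272, adjusted p = 0.657 with an estimated correlation), by small amounts such as 0.21 ± 0.07 for TRAT1 and 0.11 ± 0.03 for GZMB, both at levels under 4. After quantile normalization the adjusted p of this T cell list was 0.573, and over 13 alternatives of camera with the preset correlation it lay between 0.0164 and 0.573, with the call ended in 4 of them. At 24 h 1 of the 14 was called higher and the list did not pass (adjusted p = 0.183).

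A first hypothesis came from the fall of MARS2. Other mitochondrial tRNA synthetases may fall with it at 24 h: 12 of 14 were lower (median −1.05, adjusted p = 6.53e-09 over 12 tests, adjusted p = 0.202 with an estimated correlation), among them SARS2 (−2.40), EARS2 (−2.28) and NARS2 (−2.10). Mitochondrial ribosomal protein genes may fall as well: 60 of 72 were lower and 2 higher (median −0.81, adjusted p = 4.25e-26, adjusted p = 0.202 with an estimated correlation). At 4 h 10 and 54 genes of these groups were lower. Among genes with a mean of at least 4, the adjusted p at 24 h was 0.000562 and 3.73e-10 (0.324 for both with an estimated correlation). The 24 h arrays differ from the vehicle arrays in poly-A and hybridization spikes, which bears on these tests too.

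A second came from C5AR1 and FPR1. Whether other chemoattractant receptors rise at 24 h stays open: of 19, 4 were higher and 1 lower (median 0.07, adjusted p = 0.0442 over 12 tests, adjusted p = 0.431 with an estimated correlation), with C3AR1 at 3.15, CCR1 at 2.54, PTAFR at 1.55, CX3CR1 at 0.71 and CXCR4, the fall, at −0.16. Of the 19, 12 lay under 4 in vehicle and did not pass, at a level where 92.1% of all genes had a positive difference at 24 h, and the 7 others had a median of 0.71 (adjusted p = 0.0207, adjusted p = 0.324 with an estimated correlation). The last came from TDO2 and KYNU and stays open too: of 10 other genes of the kynurenine pathway 2 were lower and the rest did not pass, KYAT1 (−1.23) and KYAT3 (−0.32), with a median of 0.04 and a test that pointed down (adjusted p = 0.574 by limma's camera). Of these 10 genes 7 lay under 4 in vehicle and did not pass, and 3 are too few to decide (median −0.32, adjusted p = 0.446).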
